A study of Homo sapiens with 18 samples.

How the data were processed

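The samples were 18 RNA-seq libraries of 786-O cells in 6 groups of 3, mapped to groups and replicate numbers by their titles. Per the labels' protocols, total RNA was extracted with a column kit and made into libraries with a directional (strand-specific) kit, from cells grown in RPMI-1640 with serum. Per the submitters' processing notes the genome build was mm10, a mouse build, which the tables contradict: 58735 of 58735 gene identifiers of the RBCK1 and ANKRD35 tables are human Ensembl identifiers whose start and end equal those of GENCODE 29 on GRCh38. The aligner, the counting tool, the counting strand and the steps behind the scaling were not given in the sources used here. The sequences of the shRNA and siRNA were not given there either.

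The FPKM values were used as deposited; per the file headers, one table holds the RBCK1, one the ANKRD35 and one the MITD1 libraries. In the RBCK1 and ANKRD35 tables FPKM times the listed gene length was a whole multiple of one step per library, which gave the reads per gene; in the MITD1 table, which lists symbols without lengths or identifiers, each gene's own step was found from the ratios of its values. With a tolerance of 0.01 reads, 100% of values came out whole in each library of the RBCK1 and ANKRD35 tables. In the MITD1 table the step was chosen to make values whole, so that share is no check there. Gene lengths of the RBCK1 table, which the search did not use, gave one common step within 1% for 88.9% of 18028 MITD1-table genes, RBCK1, ANKRD35, MITD1 and ANXA1 among them; reads of the other genes are uncertain. The deposited FPKM values of the RBCK1 and ANKRD35 tables were scaled to library sizes 0.958 to 1.028 times the sum of reads, and a scaling between libraries moves every gene of a library alike. The MITD1 table holds 29928 symbols, of which 29892 also occur in the other tables and 11845 were at 0 in each library, and no mitochondrially encoded genes. The ANKRD35 table also holds 6 value columns that name no sample of the series, and these were not used. Its knockdown columns are named ShRNA where the sample titles say si, and were matched to the titles by target and replicate number. Reads per library, which set the counting error, are given with the results. Genes with at least 1 FPKM numbered 12075 to 12242 per library for RBCK1, 11641 to 11937 for ANKRD35 and 10277 to 10351 for MITD1.

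Replicates were compared before averaging. No columns were identical, and over genes with at least 20 reads the chi-square per gene between libraries of one group was 2.04 or more, above counting noise, so all were kept as separate libraries. Principal components were taken over the 500 most variable genes of a table. The design allowed for counts as well as for FPKM; the tables hold FPKM, so each comparison (shRBCK1 with shcontrol, siANKRD35 with sicontrol_for_siANKRD35, siMITD1 with sicontrol_for_siMITD1) was fitted with limma-trend on log2(FPKM + 1), on the 6 libraries of its own table, without a replicate block. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, two-sided, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 with no fold minimum. RBCK1, ANKRD35, MITD1 and ANXA1 were also given per library, with an exact permutation test of 3 against 3 that cannot go below p = 0.1.

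The 34 gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. They cover NF-kB targets, linear ubiquitin, p53, interferon response, antigen presentation, hypoxia, glycolysis, oxidative phosphorylation, S phase, G2/M, cytokinesis and ESCRT-III, annexins and S100, sunitinib targets and angiogenic factors, drug efflux and lysosome, ferroptosis, NRF2, YAP/TAZ, EMT and matrix, TGF-beta, MAPK and immediate early genes, ATF4 and the unfolded protein response, cholesterol, fatty acids, heat shock and proteasome, ribosomal proteins, mitochondrially encoded RNAs, histones, RNA interference, apoptosis and renal tubule identity. Markers of fibroblasts, endothelium, blood cells and an embryonic kidney line were added for other cell types. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether the members move one way on balance and makes no comparison with other genes. For called lists, camera with an estimated correlation gave larger adjusted p-values even where the estimate was below 0.01. A call lost there does not by itself show correlated members. Named genes were RBCK1, ANKRD35, MITD1 and ANXA1; per comparison the 10 genes with the largest increase and the 10 with the largest decrease among called genes whose groups did not overlap, with a mean of at least 5 FPKM in a group and an official-style symbol; the 4 members with the smallest adjusted p of each called list and 2 of each other tested list; and the 10 genes called in one direction in all 3 comparisons with the largest minimum change and a mean of at least 5 FPKM in a group of each table. Overlaps of calls were set against the product of the list sizes divided by the genes tested in both, with Fisher's exact test, two-sided. A few genes that the naming rule takes are not reported here.

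Alternatives were the replicate number as a block, a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, no trend, an adjusted p under 0.01 and leaving out each library. Chosen after seeing the data were voom of limma on the recovered reads, a correction of each library for gene length and GC content by natural splines (4 degrees of freedom), list tests without siANKRD35 replicate 2, and the MITD1 comparison without genes that hold certain 3′ UTR words. An exploratory scan asked whether genes with a seven-base word in their annotated 3′ UTR were shifted, with 999 permutations of the genes' changes. The 3′ UTRs had at least 50 bases and the words occurred in at least 100 genes. Log2 changes were limited to 2 either way and corrected for length and GC content of the 3′ UTR. As a check, the measured changes of genes with a chosen word were lowered by 0.1, for 20 words in turn. The planted word changed most in z in 20 of 20 cases. The planting nearly fixes that outcome, so it does not test the ranking by z.

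The fit was tested on simulated reads with 200 genes changed by known folds. In the RBCK1 comparison (11887 genes) it recovered 47.9% of genes changed 1.25-fold, 84% at 1.5-fold and 100% at 2-fold and 4-fold, and called 0.07% of unchanged genes. In the ANKRD35 comparison (11722 genes) it recovered 4%, 57.1%, 100% and 100%, and in the MITD1 comparison (10231 genes) 71.4%, 98%, 100% and 100%, with 0.11% of unchanged genes called in each. Far fewer genes were changed in the simulation than were called in the data, which makes its adjustment stricter. Each comparison also used a single dispersion for both groups, though siANKRD35 libraries varied more than their controls. These shares therefore do not give the recovery or the false calls in the data. Analyses used R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9; sequences and positions came from GRCh38 with GENCODE 29.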

Results

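RNA-seq was used to compare 786-O cells, an established clear cell renal carcinoma line without functional VHL, after knockdown of RBCK1, ANKRD35 or MITD1. The series title places these genes and ANXA1 on one axis downstream of the E3 ubiquitin ligase RBCK1 and links them to the response to sunitinib, a receptor tyrosine kinase inhibitor. The labels name 6 groups of 3 libraries: shRBCK1 with shcontrol, siANKRD35 with sicontrol_for_siANKRD35, and siMITD1 with sicontrol_for_siMITD1. They name no drug treatment. The columns of the ANKRD35 knockdown name shRNA where the sample titles name siRNA, so the reagent is uncertain there and the groups are called as in the titles. Each pair of groups came in its own table of FPKM values (fragments per kilobase of gene, scaled to library size), normalized separately, so every test was made within a table. Reads per library, recovered from the values, ran from 16346478 to 18648246 in the RBCK1 table, from 17502646 to 19034974 in the ANKRD35 table and from 14054066 to 15352715 in the MITD1 table. Libraries of one group correlated at 0.992 or more in the RBCK1 table, 0.97 or more in the ANKRD35 table and 0.994 or more in the MITD1 table (Pearson's r across genes). The first principal component separated knockdown from control in each table, with 81.4%, 59.5% and 78% of the variance. No pair among the 18 libraries held identical values. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Changes are given as knockdown minus control on the log2(FPKM + 1) scale, which understates changes of low genes, and values as mean FPKM ± SD with n = 3 per group. Genes named as exceptions to the direction of their list were chosen after their values were seen.

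In the shRBCK1 libraries the RNAs of interferon response, NF-kB target and antigen presentation genes fell, and many cell division genes rose by small amounts. The calls of the G2/M and S phase lists were lost in camera, with adjusted p = 0.18 and 0.23 with an estimated correlation. RBCK1, which encodes the ubiquitin ligase HOIL-1 of the linear ubiquitin chain assembly complex, measured 487, 491.7 and 462 FPKM in the shcontrol libraries and 30.83, 32.03 and 32.9 FPKM in the shRBCK1 libraries, 93.4% lower. All 39 interferon response genes tested fell, with a median log2 change of −2.99, and OAS2 fell from 69.1 ± 0.56 to 0.322 ± 0.072 FPKM. IL6, an inflammatory cytokine, fell from 52.4 ± 1.8 to 5.17 ± 0.32 FPKM, and TOP2A, the topoisomerase of dividing cells, rose from 46.7 ± 0.51 to 86.5 ± 4.2 FPKM.

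The RBCK1 gene (ENSG00000125826) lies on chromosome 20 at 407498 to 430966 of GRCh38, on the plus strand. Its log2 change was −3.87 (SE 0.038, limma adjusted p = 1.08e-09), with 96633 reads in the control group and 6945 in the knockdown group. The level in shcontrol, 480.3 ± 16 FPKM, was 6.78 and 7.33 times the levels in the control groups of the other tables, 70.8 and 65.5 FPKM, and the tables were normalized separately. ANXA1 (ENSG00000135046, chromosome 9, 73151757 to 73170393, plus strand), which encodes the phospholipid-binding protein annexin A1, fell from 144.6 ± 1.26 to 112.2 ± 4.43 FPKM. The decrease was 22.4% and was seen in 3 of 3 knockdown libraries (log2 change −0.36, SE 0.036, limma adjusted p = 0.000163). MITD1 (ENSG00000158411, chromosome 2, 99161427 to 99181058, minus strand), which encodes a protein that binds ESCRT-III in cytokinesis, was at 4.234 ± 0.0543 and 4.106 ± 0.122 FPKM and did not pass the test (log2 change −0.04, SE 0.046, limma adjusted p = 0.541). ANKRD35 (ENSG00000198483, chromosome 1, 145866560 to 145885866, minus strand) had 0 reads in the shcontrol and 1 read in the shRBCK1 libraries and was not tested.

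**Figure D1:**
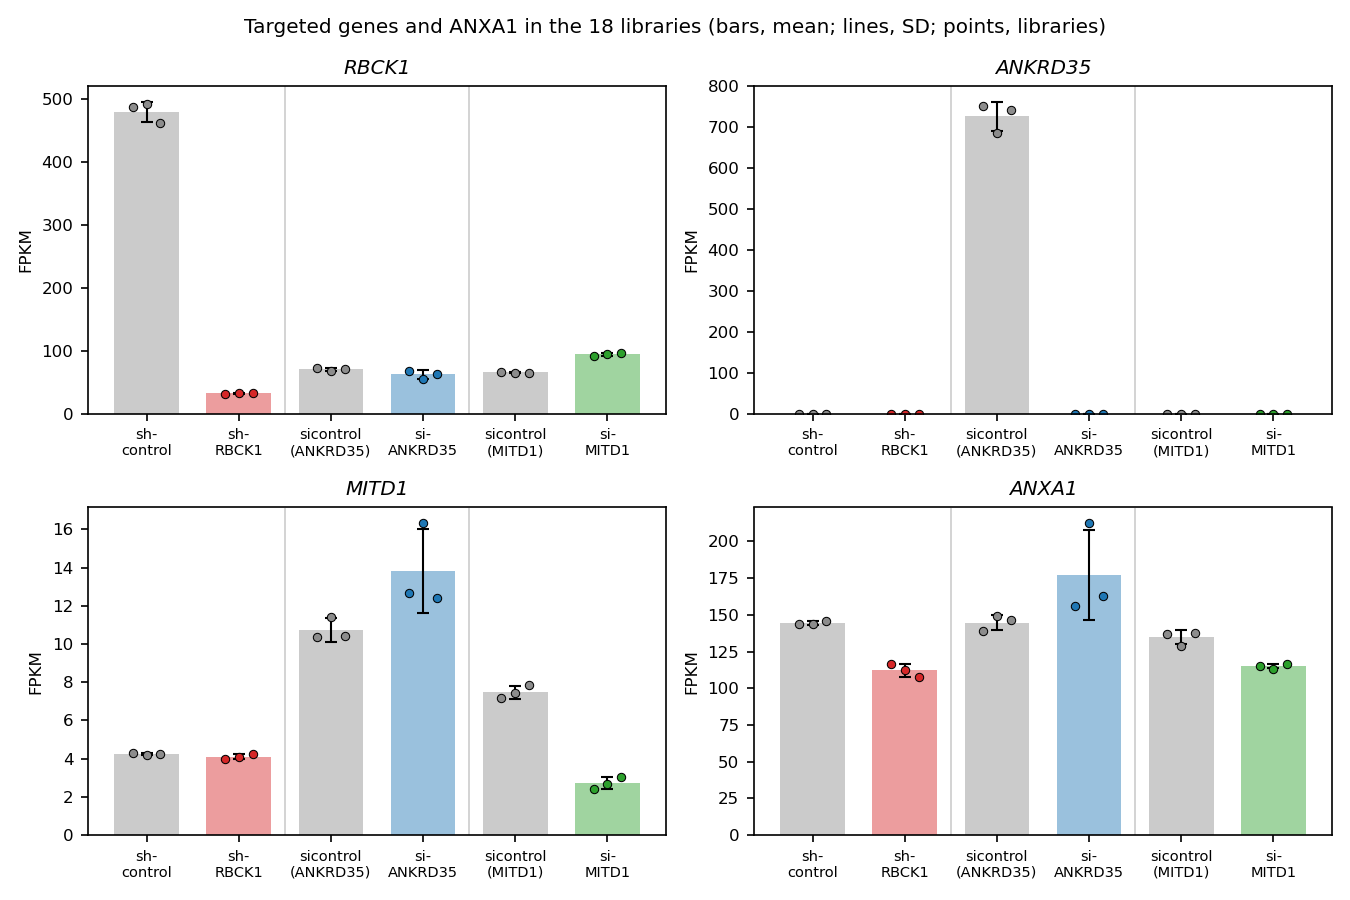
FPKM of RBCK1, ANKRD35, MITD1 and ANXA1 in the 6 groups, with bars for the group mean, lines for the SD and points for the 3 libraries of a group. RBCK1 stood at 480.3 FPKM in shcontrol and ANKRD35 at 727.4 FPKM in sicontrol_for_siANKRD35, against 70.8 FPKM or less for both genes in the other control groups; the tables were normalized separately.

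Interferon response genes held 9 of the 10 largest decreases allowed by the naming rule. The antiviral genes RSAD2 (65.9 to 1.02 FPKM), OAS1 (80.6 to 2.23 FPKM), MX2 (21.1 to 0.0385 FPKM) and OASL (118 to 4.9 FPKM) fell, as did the interferon-induced ubiquitin-like modifier ISG15 (−4.08) and IFI6 (923 to 33.6 FPKM). The median level of the list was 37.2 FPKM in shcontrol and 3.25 FPKM in shRBCK1, against 5.6 and 4.45 FPKM in the control groups of the other, separately normalized tables. The chemokine CCL5, which is outside the list, fell from 47.5 to 1.18 FPKM. Of 25 NF-kB target genes 23 fell, with a median of −0.94, among them CXCL8 (−2.88), the adhesion receptor ICAM1 (−1.69) and TRAF1 (−2.37), and TNFAIP2 (0.18) and BCL3 (0.36) rose. Of 17 antigen presentation genes 16 fell, with a median of −1.1, including the peptide transporter subunit TAP1 (110 to 21.9 FPKM) and the immunoproteasome subunit PSMB9 (−1.82). HLA-B fell by 1.27, but reads of HLA genes, of histone genes and of HSPA1B are shared with near-identical copies, so the values of those genes are uncertain.

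Targets of the Hippo pathway effectors YAP and TAZ fell in 19 of 24 cases, with a median of −0.44, among them the matricellular genes CYR61 (396 to 161 FPKM) and CTGF (−1.56) and the repeat protein gene ANKRD1 (−2.41). PTPN14, YAP1 and TEAD1, also on the list, rose. Of 32 ATF4 and unfolded protein response genes 24 fell, with a median of −0.52: the chaperone HSPA5 fell from 377 to 165 FPKM, PPP1R15A by 2.37 and ATF4 by 1.02, and SEL1L, DDIT4 and VLDLR rose. Of 25 MAPK and immediate early genes 19 fell and 2 rose, with a median of −0.53, and ATF3 (28.4 to 1.82 FPKM), the phosphatase DUSP1 (−1.64) and MYC (83.1 to 35.6 FPKM) fell. Of 13 linear ubiquitin genes, a list that holds the target RBCK1 itself, 10 fell and the deubiquitinase OTULIN (0.14) rose; RNF31, the catalytic ligase of the complex, fell from 7.2 to 4.5 FPKM and TNIP1 by 0.91. Of 26 apoptosis regulators 14 fell and 4 rose, with a median of −0.18, among them PMAIP1 (116 to 32.8 FPKM) and MCL1 (−0.68). Of 8 histone genes 4 fell, with HIST1H1E at −2.11 and HIST2H2BE at −0.89.

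Many cell division genes rose, in list calls that were lost in camera, as were those of the oxidative phosphorylation and mitochondrially encoded lists (adjusted p = 0.18 for G2/M, 0.23 for S phase, 0.49 and 0.48 with an estimated correlation). Of 39 G2/M genes 31 rose, 1 fell and 7 did not pass, with a median of 0.22, and the kinesins KIF20A (0.68) and KIF11 (0.54) rose with TOP2A. Of 40 S phase genes 26 rose, 2 fell and 12 did not pass, with a median of 0.23, among them RRM2 (0.51), MCM6 (0.51) and PCNA (78.9 to 102 FPKM). Of 29 nuclear-encoded oxidative phosphorylation genes 15 rose and 0 fell, with a median of 0.16, such as ATP5PB (0.3) and SDHA (0.24). Of 13 mitochondrially encoded RNAs 10 rose, with a median of 0.21; the counting strand is not stated, so overlapping or opposite-strand RNAs such as MT-ND5 (0.42), MT-ND6 (0.54) and MT-ATP8 (0.77) are uncertain. Mitochondrially encoded genes held 2.38% ± 0.08 of the reads in shcontrol and 2.83% ± 0.04 in shRBCK1 (SD, n = 3). Among the 10 largest increases were those of the potassium channel gene KCNJ16 (1.42 to 5.76 FPKM), SIGLEC15 (8.39 to 23.1 FPKM), the cytochrome CYP1B1 (11 to 25.6 FPKM) and the cell cycle inhibitor CDKN2C (15.9 to 34.6 FPKM).

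By limma 6000 of 12227 genes passed an adjusted p of 0.05 in the RBCK1 comparison, 2951 higher and 3049 lower, of which 35 rose and 247 fell at least 2-fold; the libraries of the groups did not overlap for 59% of genes tested, where chance gives 10%. The balance turned under quantile normalization, with 3501 higher and 2649 lower, and with the length and GC correction, with 3595 and 2780. Of 30 lists tested with camera, 4 were higher and 9 lower. The camera adjusted p was 2.1e-35 for interferon response, 1.6e-12 for NF-kB targets, 3.4e-10 for antigen presentation and 7.9e-07 for each of the YAP/TAZ, ATF4 and MAPK lists. It was 0.00017 for the linear ubiquitin, 0.0097 for the apoptosis, 0.039 for the histone, 4.8e-08 for the G2/M, 7.3e-06 for the S phase, 0.0078 for the oxidative phosphorylation and 0.011 for the mitochondrially encoded list. With an estimated correlation the calls held for interferon (adjusted p = 0.019), NF-kB (0.032), antigen presentation (0.035), YAP/TAZ (0.035) and ATF4 (0.042) in camera. The other calls were lost, with camera adjusted p = 0.052 (MAPK), 0.093 (linear ubiquitin), 0.12 (apoptosis), 0.22 (histones), 0.18 (G2/M), 0.23 (S phase), 0.49 (oxidative phosphorylation) and 0.48 (mitochondrially encoded) with an estimated correlation. Among these lost calls the estimates were below the preset 0.01 for apoptosis (0.002) and histones (0.008). They were above it for the rest, up to 0.408 for mitochondrially encoded RNAs. Adjusted over the list alone, 4 rose and 24 fell in the ATF4 list, 3 and 19 in MAPK, 1 and 11 in linear ubiquitin, 4 and 15 in apoptosis, 33 and 1 in G2/M, 26 and 3 in S phase and 10 and 1 in the mitochondrially encoded list, and the other called lists gave the same counts. In the RBCK1 knockdown the histone call was also lost with voom (camera adjusted p = 0.072) and without shRBCK1 replicate 1 (0.054), and the mitochondrially encoded call under quantile normalization (0.3); over the camera settings other than the estimated correlation their adjusted p ran from 0.011 to 0.072 and from 0.005 to 0.3.

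The remaining 17 lists did not pass in the RBCK1 comparison, and counts adjusted over the list alone differed by at most 3 members. Higher and lower members were 5 and 11 of 22 p53 targets, 8 and 10 of 29 hypoxia genes, 2 and 3 of 18 glycolysis genes, 6 and 8 of 24 cytokinesis genes and 5 and 5 of 17 annexin and S100 genes. They were 4 and 6 of 14 sunitinib targets and angiogenic factors, 9 and 7 of 28 drug efflux and lysosome genes, 5 and 10 of 21 ferroptosis genes, 4 and 11 of 22 NRF2 targets, 6 and 10 of 28 EMT and matrix genes and 8 and 11 of 22 TGF-beta response genes. They were 11 and 3 of 24 cholesterol genes, 10 and 6 of 24 fatty acid genes, 7 and 7 of 26 heat shock and proteasome genes, 12 and 2 of 36 ribosomal protein genes, 4 and 4 of 14 RNA interference genes and 5 and 4 of 11 renal tubule genes. The smallest camera adjusted p among them was 0.076, for NRF2 targets. The median, mean and test direction differed in sign for RNA interference (0.02, −0.06, up) and renal tubule genes (−0.07, 0.02, up), and the mean was 0 for the annexin and efflux lists. Single members still moved: VEGFA, the angiogenic ligand, rose from 26.6 to 50.5 FPKM and the desaturase SCD from 65.3 to 132 FPKM, while GADD45A (218 to 54.8 FPKM) and HMOX1 (112 to 28.1 FPKM) fell. Marker lists of other cell types had too few members for a test: LUM rose (0.25) and PDPN fell (−0.35) among 2 fibroblast genes, EGFL7 did not pass, LAPTM5 rose (0.42) as the 1 blood cell gene, and GATA3 (−0.32) fell among 3 embryonic kidney line genes.

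In the siANKRD35 libraries many genes of respiration, ribosomes and the proteasome rose, and many interferon response, YAP/TAZ, TGF-beta and cholesterol genes fell, in list tests that did not hold with an estimated correlation. ANKRD35, which encodes an ankyrin repeat protein, measured 753.2, 687.1 and 742 FPKM in the sicontrol_for_siANKRD35 libraries and 0, 0 and 0.03317 FPKM in the siANKRD35 libraries. Nuclear-encoded oxidative phosphorylation genes rose in 26 of 29 cases, with a median log2 change of 0.56. SFN, the epithelial 14-3-3 sigma protein gene, rose from 2.67 ± 0.32 to 36 ± 11 FPKM, and the growth factor response gene EGR1 fell from 10.6 ± 0.29 to 1.24 ± 0.13 FPKM.

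For ANKRD35 the control group held 135649 reads and the knockdown group 2, a ratio of 67353 after adjustment for library size (95% interval 18645 to 556158, counting error only; reads from PCR without molecular identifiers are not independent molecules). The log2 change was −9.49 (SE 0.069, limma adjusted p = 3.12e-09). The control level of 727.4 ± 35.4 FPKM stood against 0 and 0.0064 FPKM in the other control groups, whose tables were normalized separately. ANKRD35 had 0 reads in shcontrol, 1 in shRBCK1, 1 in sicontrol_for_siMITD1 and 3 in siMITD1, about as few as in siANKRD35. The ratio thus rests on a control level that no other control group reached. The other genes of the axis did not pass the test, though some did under alternatives given below. RBCK1 was at 70.76 ± 2.44 and 62.11 ± 6.93 FPKM (log2 change −0.19, SE 0.095, limma adjusted p = 0.156), MITD1 at 10.73 ± 0.616 and 13.8 ± 2.19 FPKM (0.33, SE 0.114, limma adjusted p = 0.0618) and ANXA1 at 144.8 ± 5.08 and 177.3 ± 30.7 FPKM (0.28, SE 0.122, limma adjusted p = 0.116). The siANKRD35 libraries gave 156.2, 212.5 and 163.1 FPKM of ANXA1, each above the 3 controls; an exact permutation test of 3 against 3 gave p = 0.1, two-sided, the smallest it allows. In the ANKRD35 comparison quantile normalization moved RBCK1 to −0.44 (limma adjusted p = 0.00766, range over settings 0.00766 to 0.354), the length and GC correction moved it to −0.24 (limma adjusted p = 0.0106), and quantile normalization moved ANXA1 to −0.1 (limma adjusted p = 0.622, range 0.0546 to 0.622). Without siANKRD35 replicate 2 MITD1 was at 0.21 (limma adjusted p = 0.0282), with a length and GC correction at 0.18 (0.0385) and with voom at 0.35 (0.0498), with a range over settings of 0.0282 to 0.174.

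Changes in the ANKRD35 comparison ran with gene length: Spearman's rho of log2 change and length was −0.41 across genes, against 0.03 and 0.09 in the RBCK1 and MITD1 comparisons. Genes under 2000 bases (1946 genes) had a median change of 0.26 and genes over 6000 bases (4069 genes) of −0.14. The siANKRD35 libraries also varied more among themselves, with pairwise r of 0.97 to 0.99, and the deviation of replicate 2 from its group ran with GC content at rho −0.73 across genes, against 0.67 and 0.44 for replicates 1 and 3. The list medians below are therefore given as measured and after a correction of each library for length and GC content.

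Oxidative phosphorylation genes (0.56, corrected 0.46) included SDHB of complex II (37.2 to 61.3 FPKM), COX5A (0.92) and ATP5MC1 (0.66). Of 36 ribosomal protein genes 27 rose and 0 fell (median 0.45, corrected 0.35, and 0.14 with 6 higher under quantile normalization), such as RPL27 (282 to 507 FPKM) and RPL22 (0.68). Of 26 heat shock and proteasome genes 21 rose (0.47, corrected 0.37), among them the proteasome assembly factor POMP (83.2 to 138 FPKM) and PSMA5 (0.66). Of 17 glycolysis genes 11 rose (0.43, corrected 0.37), with PGAM1 at 0.62 and hexokinase HK2 at 0.7. Of 39 G2/M genes 16 rose and 3 fell (0.31, corrected 0.18): UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, rose from 62.3 to 133 FPKM and CDK1 by 1.26. Of 39 S phase genes 14 rose and 0 fell (0.22, corrected 0.09), including CDC45 (0.51) and FEN1 (0.61).

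Of 30 interferon response genes 16 fell and IFI6 (0.36) rose (median −0.43, corrected −0.4); OASL fell from 18.6 to 4.55 FPKM, IFIT3 from 55.7 to 22.8 FPKM and RSAD2 by 1.9. Of 25 YAP/TAZ targets 16 fell and 3 rose (−0.41, corrected −0.34), with ANKRD1 at −0.85 and TGFB2 at −1.14. Of 22 TGF-beta response genes 11 fell and 1 rose (−0.34, corrected −0.31), among them the cell cycle inhibitor CDKN2B (−1.27) and KLF10 (−0.98). Of 24 cholesterol synthesis genes 10 fell and EBP (0.62) rose (−0.28, corrected −0.32), including HMGCS1 (−1.34) and the sterol sensor INSIG1 (−1.15). Of 33 ATF4 and unfolded protein response genes 12 fell and 2 rose (−0.27, corrected −0.27), such as HERPUD1 (57.4 to 27.8 FPKM) and the chaperone HYOU1 (−0.94). Of 28 EMT and matrix genes 12 fell and 4 rose (−0.2, corrected −0.18): fibronectin, FN1, fell from 67.5 to 23.9 FPKM and COL4A1 by 1.28, while the collagenase MMP1 (8.19 to 55.8 FPKM), TIMP1, LOX and TWIST2 rose. Of 10 histone genes 4 fell (−0.36, corrected −0.6), with HIST1H2AC at −0.75. Of 27 p53 targets 10 fell and 3 rose (−0.19, corrected −0.3): BTG2 (−0.84) and MDM2 (−0.92) fell, and the stress cytokine GDF15 (452 to 869 FPKM), PLK2 and BAX rose.

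By limma 4312 of 11890 genes passed in the ANKRD35 comparison, 2305 higher and 2007 lower, of which 74 rose and 90 fell at least 2-fold; the groups did not overlap for 52.2% of genes (10% by chance). Single libraries moved the count: it was 2324, 2267 and 2358 without control replicates 1, 2 and 3, 2825 without siANKRD35 replicate 3 and 6536 without siANKRD35 replicate 2. The balance turned under quantile normalization (1675 higher and 2036 lower) and median-ratio scaling (2056 and 2177). Of 30 lists 6 were higher and 8 lower with camera. The camera adjusted p was 7.4e-10 for oxidative phosphorylation, 2.1e-08 for ribosomal proteins, 1e-06 for heat shock and proteasome, 0.00057 for glycolysis, 0.00079 for G2/M and 0.0068 for S phase. It was 6.9e-06 for interferon response, 3.4e-05 for YAP/TAZ, 2e-04 for TGF-beta, 0.00096 for cholesterol, 0.0032 for ATF4, 0.007 for EMT, 0.019 for histones and 0.027 for p53. No call held with an estimated correlation: camera gave adjusted p = 0.37 for G2/M, 0.15 for glycolysis, S phase, ATF4, histones and p53 and 0.12 for the other 8 lists with an estimated correlation. The estimates were below the preset 0.01 for histones (−0.037), cholesterol (−0.034), EMT (−0.02) and p53 (0.009). They were above it for the other called lists, up to 0.226 for G2/M. Adjusted over the list alone, members higher and lower were 28 and 0 (oxidative phosphorylation), 31 and 0 (ribosomal), 23 and 1 (heat shock and proteasome), 18 and 3 (G2/M), 1 and 17 (interferon), 3 and 17 (YAP/TAZ), 2 and 11 (TGF-beta), 2 and 13 (ATF4), 4 and 13 (EMT) and 1 and 4 (histones), and the other called lists kept their counts. In the ANKRD35 knockdown the S phase call was lost with the length and GC correction (camera adjusted p = 0.07, range over the camera settings 0.0061 to 0.073) and under quantile normalization (0.073), and the glycolysis call under quantile normalization (0.076, range 1.6e-05 to 0.076). Without siANKRD35 replicate 2 the p53 (camera adjusted p = 0.063, range 0.0014 to 0.063) and histone calls (0.084, range 0.0043 to 0.084) were lost.

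The other 16 lists tested did not pass in the ANKRD35 comparison, and counts adjusted over the list alone differed by at most 3 members. Higher and lower members were 11 and 8 of 28 NF-kB targets, 2 and 3 of 13 linear ubiquitin genes, 3 and 3 of 16 antigen presentation genes, 10 and 2 of 28 hypoxia genes, 3 and 2 of 24 cytokinesis genes and 5 and 1 of 15 annexin and S100 genes. They were 1 and 4 of 14 sunitinib targets, 6 and 8 of 27 efflux and lysosome genes, 4 and 2 of 21 ferroptosis genes, 6 and 6 of 22 NRF2 targets and 6 and 8 of 26 MAPK genes. They were 7 and 9 of 22 fatty acid genes, 0 and 1 of 13 mitochondrially encoded RNAs, 1 and 3 of 11 RNA interference genes, 6 and 4 of 27 apoptosis regulators and 4 and 2 of 10 renal tubule genes. The smallest camera adjusted p among them were 0.051 for hypoxia and 0.056 for annexins. The median was above 0 while the test pointed down for the efflux (median 0.02, mean −0.01), fatty acid (0.05, −0.06) and apoptosis (0.01, mean 0.06) lists. The antioxidant enzyme HMOX1 rose from 169 ± 10 to 697 ± 200 FPKM, the lipid droplet protein PLIN2 from 17.5 to 47.7 FPKM and ANXA2 from 167 to 239 FPKM, while SCD (26 to 7.01 FPKM) and the fatty acid synthase FASN (22.2 to 7.61 FPKM) fell. Mitochondrially encoded genes held 6.18% ± 0.1 of the reads in the control and 5.73% ± 0.69 in the knockdown libraries. Of other cell types' markers, 0 of 2 fibroblast genes passed, EGFL7 (0.72) rose as the 1 endothelial gene, LGR5 (0.52) rose and NEFL (−0.73) fell as the 2 embryonic kidney line genes, and blood cell markers had 0 genes past the filter.

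**Figure D2:**
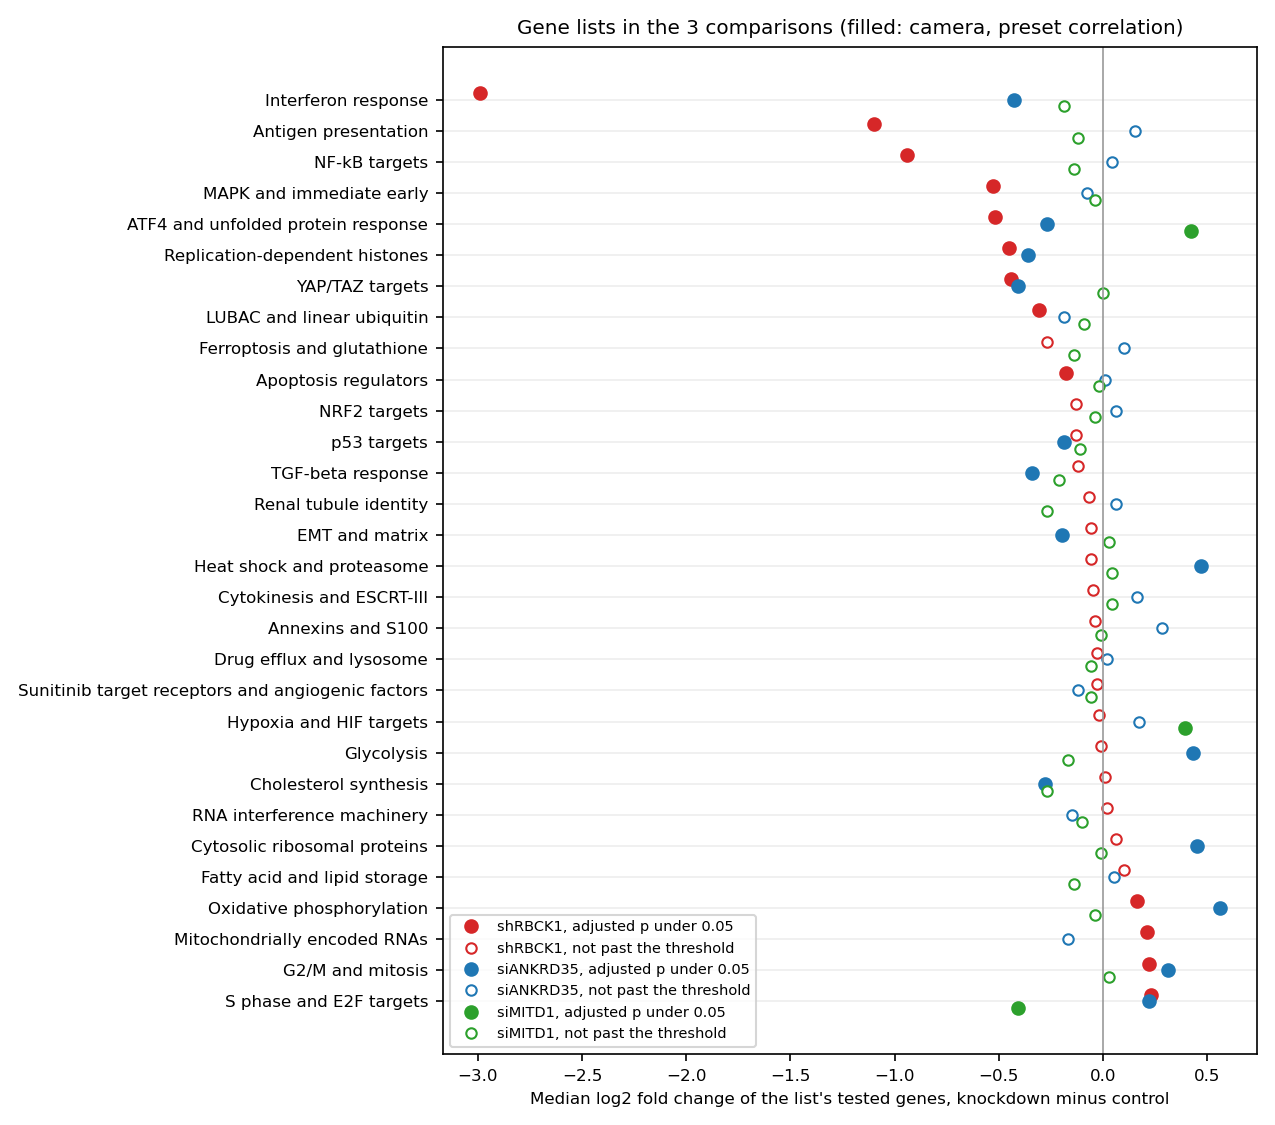
Median log2 change (knockdown minus control, log2(FPKM + 1) scale) of each gene list tested in the 3 comparisons, with filled points where the camera adjusted p with the preset correlation was under 0.05. In the RBCK1 comparison the interferon response list stood lowest, at −2.99. Its medians were −0.43 and −0.19 in the ANKRD35 and MITD1 comparisons, and the S phase list stood lower in the MITD1 comparison, at −0.41. The interferon call of the ANKRD35 comparison was lost in camera (adjusted p = 0.12 with an estimated correlation), and the interferon list did not pass in the MITD1 comparison.

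In the siMITD1 libraries many genes of the ATF4 and unfolded protein response (26 of 32) and of the hypoxia list (19 of 29, with 7 lower) rose and many S phase genes (32 of 40, with 3 higher) fell, in list tests that did not hold with an estimated correlation. MITD1 measured 7.16, 7.423 and 7.828 FPKM in the sicontrol_for_siMITD1 libraries and 2.434, 2.659 and 3.033 FPKM in the siMITD1 libraries, 63.7% lower. The stress transcription factor DDIT3 rose from 6.32 ± 0.69 to 23 ± 1.1 FPKM and NDRG1, a hypoxia-induced gene, from 35.6 ± 0.13 to 96.3 ± 1.1 FPKM. TK1, the thymidine kinase of S phase, fell from 126 ± 3 to 58 ± 1.6 FPKM. The largest decrease under the naming rule was that of EDN2, which encodes the vasoactive peptide endothelin 2, from 28.8 ± 2 to 2.37 ± 0.21 FPKM.

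The log2 change of MITD1 was −1.19 (SE 0.069, limma adjusted p = 1.56e-06), from 1411 reads in the control and 536 in the knockdown group. RBCK1 rose from 65.46 ± 0.96 to 94.52 ± 2.43 FPKM in 3 of 3 knockdown libraries, 44.4% higher (log2 change 0.52, SE 0.029, limma adjusted p = 1.19e-06). ANXA1 fell from 134.6 ± 4.73 to 114.9 ± 1.47 FPKM in 3 of 3 knockdown libraries, 14.6% lower (−0.23, SE 0.03, limma adjusted p = 0.000217). ANKRD35 had 1 read in the control and 3 in the knockdown libraries and was not tested. Whether the changes of ANXA1 differed between the comparisons was not tested. The 3′ UTR of ANXA1 holds the eight-base word TTCTTCAA (chromosome 9, 73170187 to 73170194). On average 546 genes with that word were shifted by −0.132 ± 0.018 (SE) after correction for 3′ UTR length and GC content, against 0.032 in 7186 genes without its parts. Among genes named for the MITD1 comparison, both seven-base parts of the word also occur in the 3′ UTRs of HAS3, PAX8, PGK1 and INHBA, and one of them in those of TK1, CCND1, SPARC, TAGLN3 and TP53INP2. A part of the word occurs in 25.4% of the 9638 genes searched, 29.4% of those called lower and 22.4% of those called higher. Of genes with the whole word 61.5% were lower, against 52.7% of genes with neither part, so it says little about single genes. MKNK2 holds one of the words found more often in genes that rose.

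Of 32 ATF4 and unfolded protein response genes 26 rose and 2 fell, with a median of 0.42. Besides DDIT3, the pseudokinase TRIB3 rose from 48.5 to 147 FPKM, DDIT4 from 270 to 535 FPKM and the chaperone HSPA5 from 328 to 493 FPKM, while PDIA4 and SDF2L1 fell by 0.14 each. Of 29 hypoxia genes 19 rose and 7 fell, with a median of 0.39: IGFBP3 (270 to 622 FPKM) and VEGFA (39.6 to 82.8 FPKM) rose. The hypoxia genes that fell were CCND1 (235 to 131 FPKM), SLC2A1, AK4, PFKFB3, PFKFB4, PDK1 and KDM3A, of which SLC2A1, AK4, PFKFB3, PFKFB4 and PDK1 act in glucose uptake and energy metabolism. Of 40 S phase genes 32 fell, with a median of −0.41, including the helicase subunit MCM4 (−0.74), the checkpoint adaptor CLSPN (−0.93) and FEN1 (−0.72), and 3 rose, among them E2F1 (0.42) and RRM1 (0.18). Among the 10 largest increases were those of the BMP antagonist NOG (5.54 to 27.8 FPKM), GDF15 (5.62 to 24.5 FPKM), MKNK2 (30.2 to 88.8 FPKM) and INHBA (1.51). The chromatin protein HMGA1 (37.9 to 7.38 FPKM), the haem transporter SLC48A1 (−1.96), TAGLN3 (−1.95), the hyaluronan synthase HAS3 (54.8 to 16.1 FPKM) and TP53INP2 (−1.55) fell.

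By limma 6835 of 10415 genes passed in the MITD1 comparison, 3124 higher and 3711 lower, of which 96 rose and 137 fell at least 2-fold; the groups did not overlap for 70.4% of genes (10% by chance). Under quantile normalization 3412 were higher and 3399 lower. Of 28 lists tested, camera called ATF4 (adjusted p = 7.7e-08) and hypoxia (0.0028) higher and S phase (1.6e-05) lower. None held with an estimated correlation, where camera gave adjusted p = 0.064 for ATF4, 0.14 for hypoxia and 0.064 for S phase with an estimated correlation. The estimates were 0.01, −0.013 and −0.014, no higher than the preset 0.01, so a higher correlation among members was not why these calls were lost. In the RBCK1 comparison the YAP/TAZ list had an estimate of −0.007, yet its camera adjusted p rose from 7.9e-07 to 0.035. The test with an estimated correlation was thus stricter apart from the correlation itself. A call lost there is not by itself evidence of correlated members. Counts adjusted over the list alone were the same for these lists and differed by at most 1 member for the 25 others. Interferon response genes (4 higher and 15 lower of 26) and cholesterol genes (5 and 15 of 25) each had a camera adjusted p of 0.063, glycolysis genes (3 and 12 of 18) of 0.14 and renal tubule genes (1 and 6 of 11) of 0.41. The glycolytic kinase PGK1 fell from 217 to 84.2 FPKM and the renal lineage factor PAX8 from 35 to 18.6 FPKM.

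The other 21 lists of the MITD1 comparison had a camera adjusted p of 0.94. Higher and lower members were 9 and 12 of 24 NF-kB targets, 3 and 5 of 12 linear ubiquitin genes, 6 and 12 of 25 p53 targets, 2 and 5 of 11 antigen presentation genes, 5 and 8 of 25 oxidative phosphorylation genes, 13 and 13 of 39 G2/M genes and 7 and 8 of 24 cytokinesis genes. They were 6 and 4 of 16 annexin and S100 genes, 4 and 7 of 14 sunitinib targets, 5 and 9 of 25 efflux genes, 9 and 10 of 21 ferroptosis genes, 7 and 8 of 22 NRF2 targets, 9 and 10 of 23 YAP/TAZ targets and 13 and 10 of 30 EMT genes. They were 7 and 11 of 21 TGF-beta genes, 9 and 11 of 23 MAPK genes, 6 and 12 of 22 fatty acid genes, 10 and 7 of 24 heat shock and proteasome genes, 9 and 11 of 35 ribosomal protein genes, 5 and 7 of 14 RNA interference genes and 8 and 10 of 27 apoptosis regulators. Median, mean and test direction differed in sign, or one was 0, for the G2/M, cytokinesis, annexin, ferroptosis, NRF2, YAP/TAZ, ribosomal and apoptosis lists, with medians from −0.14 to 0.04. Members that rose included ICAM1 (27 to 58.8 FPKM), CXCL8 (12.8 to 25.7 FPKM) and CTH (1.22), and SPARC (−0.87) and the cell death effector BAK1 (−1.14) fell. The table has no mitochondrially encoded genes and no members of the histone list. Of other cell types' markers, 0 of 3 fibroblast genes passed, EGFL7 (−0.75) fell as the 1 endothelial and LAPTM5 (−1.2) as the 1 blood cell gene, and WT1 (−1.14) and NEFL (−0.33) fell among 3 embryonic kidney line genes.

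The knockdowns were compared by the genes called in each, since the series title puts their targets on one axis and no control library was shared. RBCK1 and ANKRD35 knockdown lowered 716 genes in common where 476 were expected by chance (Fisher's exact test, two-sided, p = 8e-42) and raised 601 where 525 were expected (p = 2.4e-05), among 10637 genes tested in both. The test takes genes as independent, which they are not, so here and below its p-values do not measure the spread between libraries. In opposite directions went 800 genes, against 1005 by chance. The count in one direction, 1317, was 738, 741 and 779 without ANKRD35 control replicates 1, 2 and 3, with 434, 437 and 450 lower in both against 263, 258 and 270 by chance. RBCK1 and MITD1 knockdown raised 807 genes in common against 768 by chance (Fisher's exact p = 0.054) and lowered 944 against 930 (p = 0.49), among 10021 genes. For this pair 1825 went in opposite directions, against 1696 by chance. ANKRD35 and MITD1 knockdown shared fewer genes than chance gives, 486 higher against 564 (Fisher's exact p = 1e-05) and 524 lower against 617 (p = 1.5e-07), with 1441 in opposite directions against 1198. The 1010 in one direction became 513, 515 and 547 without ANKRD35 control replicates 1, 2 and 3 and 665 without siANKRD35 replicate 3. Spearman's rho of the log2 changes was 0.13, −0.02 and −0.1 for the 3 pairs, across genes, which are not independent replicates. In all 3 comparisons 158 genes rose (143 by chance) and 204 fell (161 by chance), among 9262 genes. Among the 10 genes called in one direction in all 3 with the largest minimum change were OASL (−4.34, −1.83 and −1.39 in the RBCK1, ANKRD35 and MITD1 comparisons), the thioredoxin-binding protein TXNIP (−0.72, −1.77 and −1.54), IFIT1 (−3.62, −0.84 and −0.71), LTBP2 (−0.59, −0.69 and −0.61), SERTAD1 (−0.9, −0.57 and −0.91), ZFP36L2 (−0.89, −0.57 and −0.7), CDKN2AIP (−0.76, −0.57 and −0.54), ZNF319 (−0.5, −0.82 and −0.77) and the NF-kB inhibitor TNFAIP3 (−2.03, −0.52 and −0.66). The 3′ UTR of TNFAIP3 holds parts of the word TTCTTCAA, and that of LTBP2 holds words found more often in genes that rose in the MITD1 comparison.

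**Figure D3:**
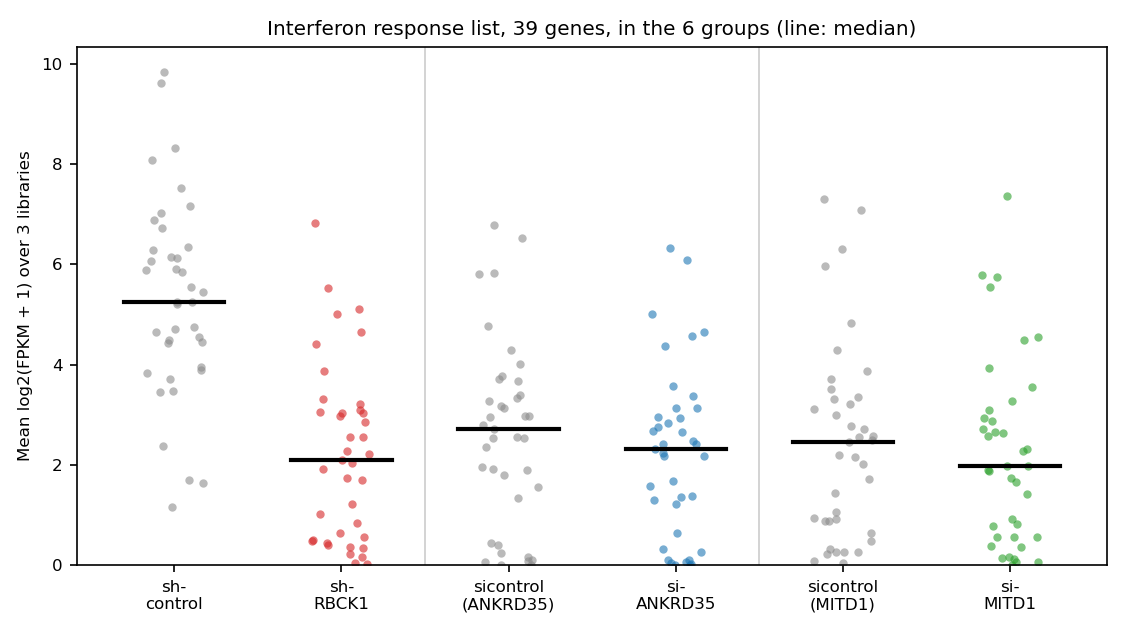
Mean log2(FPKM + 1) of the 39 interferon response genes in each of the 6 groups, a point per gene and a line at the median. The shcontrol group stood above the others, with a median level of 37.2 FPKM against 2.92 to 5.6 FPKM; the tables were normalized separately.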

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

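The voom fits, the length and GC corrections, the list tests without siANKRD35 replicate 2 and the fit without 3′ UTR words were chosen after the data had been seen. Of the counts of called genes and of overlaps recomputed under the alternatives, 83 stayed within 1.5 times the reported value and 17 moved further. With an adjusted p under 0.01 limma called 3967 genes in the RBCK1 and 1932 in the ANKRD35 comparison, and the genes called in the same direction were 455 (300 by chance) for RBCK1 and ANKRD35, 1009 (923) for RBCK1 and MITD1 and 376 (436) for ANKRD35 and MITD1, as a stricter threshold must lower a count. Leaving out one library gave 4952 to 5471 genes in the RBCK1, 2267 to 6536 in the ANKRD35 and 6324 to 6432 in the MITD1 comparison. Counts without each ANKRD35 library that moved them are given with the result; the cause was not tested. The overlap of RBCK1 and ANKRD35 then ran from 738 to 1803, that of RBCK1 and MITD1 from 1453 to 1665 and that of ANKRD35 and MITD1 from 513 to 1505. Observed over chance stayed above 1 for RBCK1 and ANKRD35 (1.18 to 1.52) and below 1 for ANKRD35 and MITD1 (0.82 to 0.9) in every alternative run, and that of RBCK1 and MITD1 ran from 0.99 to 1.09. The replicate block gave 5347, 4139 and 6859 genes and changed no list call; same-numbered libraries did not deviate together (correlations of −0.01, 0.01 and 0.03 in the RBCK1, 0.18, 0.11 and −0.09 in the ANKRD35 and 0.1, 0.03 and 0 in the MITD1 table), and not every library correlated best with its own number, so the numbers do not pair the samples. Without a filter limma called 4984, 3053 and 6807 genes, with voom 6577, 4613 and 7091, after the length and GC correction 6375, 5252 and 6770, and under quantile normalization 6150, 3711 and 6811. Quantile normalization kept 5535 of the 6000 RBCK1 calls and turned 3, and the length and GC correction turned 4 of the MITD1 calls. Of the named genes' changes 1305 of 1305 kept their side of the threshold in the MITD1, 1707 of 1720 in the RBCK1 and 1636 of 1682 in the ANKRD35 comparison. ANXA1 in the ANKRD35 comparison reversed under quantile normalization, to −0.098 (limma adjusted p = 0.622); the cause was not tested. MITD1 there passed with the replicate block (limma adjusted p = 0.0406), with voom (0.0498), with the length and GC correction (0.0385) and without siANKRD35 replicate 2 (0.0282), and RBCK1 with the length and GC correction (0.0106) and under quantile normalization (0.00766). The RNA interference list in the RBCK1 comparison and the sunitinib target list in the MITD1 comparison pointed the other way with fry (adjusted p = 0.0116 down and 0.0219 up), which tests the balance of directions rather than the list against other genes. With an estimated correlation 5 of 13, 0 of 14 and 0 of 3 list calls held in the RBCK1, ANKRD35 and MITD1 comparisons. Uncalled lists that passed under camera alternatives were, in the RBCK1 knockdown, ribosomal proteins (quantile normalization, camera adjusted p = 2.1e-05, length and GC correction 0.011, without shRBCK1 replicate 1 0.025) and ferroptosis (quantile normalization, 0.049). In the ANKRD35 knockdown they were hypoxia (length and GC correction, camera adjusted p = 0.0066, without control replicate 3 0.035), MAPK (length and GC correction 0.033, quantile normalization 0.0091), annexins (without siANKRD35 replicate 2 0.027, replicate 3 0.046), RNA interference (without siANKRD35 replicate 2, 0.048) and mitochondrially encoded RNAs, lower (length and GC correction 0.00034, quantile normalization 0.013, without siANKRD35 replicate 2 0.01). In the MITD1 knockdown it was interferon response (length and GC correction, camera adjusted p = 0.049, without siMITD1 replicate 3 0.033, genes without the 3′ UTR words 0.022). With fry 11 of 17, 7 of 16 and 12 of 25 uncalled lists also passed in the RBCK1, ANKRD35 and MITD1 comparisons. Splits of the 6 libraries of a table number 10, too few for a share under 0.05: the real split called 6000, 4312 and 6835 genes in the RBCK1, ANKRD35 and MITD1 comparisons and the highest of the others 1, 1 and 0, so 1 split of 10 reached the real count in each. For lists with the preset correlation the real split gave 13, 14 and 3 calls and the highest other split 12, 14 and 3, so that 1, 2 and 2 splits of 10 gave as many. Each other split divided the groups unevenly and kept part of their difference, so these list counts decide nothing. For the overlaps 1 of 100 pairs of splits, the real one, gave as many genes (1317, 1751 and 1010, with 0 in the highest other); the other splits called at most 1 gene, which fixed their overlaps, so this decides nothing. Of the smallest simulated changes 4% were recovered in the ANKRD35 comparison, and 71.4% in the MITD1 comparison, whose libraries had fewer reads and a smaller simulated dispersion (0.00132 against 0.0108), so depth was not shown to be the limit. Alternatives written for count tables, and a limma fit on FPKM beside counts, were not run, since the tables hold FPKM.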

Other observations

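All tests of the 3 patterns weighed below were chosen after the patterns were seen, and only the 2 tests of eight-base words were set before the value they measure was seen. Some named genes moved one way after one knockdown and the other way after another, though the difference between comparisons was not tested. PPP1R15A fell by 2.37 in the shRBCK1 and rose by 1.6 in the siMITD1 libraries, and changes there were −1.19 and 0.59 for HSPA5, −1.69 and 1.1 for ICAM1 and −2.88 and 0.95 for CXCL8. VEGFA rose in both (0.9 and 1.05). Between the RBCK1 and ANKRD35 comparisons, HMOX1 moved by −1.96 and 2, PLIN2 by −0.58 and 1.39, SCD by 1 and −1.75 and KRT18, a simple epithelial keratin, by −0.44 and 0.81. These genes were picked for contrast after their values were seen.

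Other named genes with large changes belong to no list. In the siANKRD35 libraries the chemokine receptor CXCR4 rose from 1.88 to 10.4 FPKM, the decoy receptor IL13RA2 from 3.94 to 16.2 FPKM, the kinetochore gene KNSTRN from 24.5 to 91.1 FPKM and the homeobox gene HOXB13 from 4.17 to 14.6 FPKM, while COL7A1 fell from 7.06 to 1.71 FPKM and the basement membrane proteoglycan HSPG2 from 5.77 to 1.66 FPKM. KRTAP2-3 rose there from 2.28 to 9 FPKM, uncertain because near-identical copies share its reads. In the shRBCK1 libraries the integrin ITGB8 rose from 2.95 to 7.15 FPKM and the clock output factor TEF from 3.28 to 8.09 FPKM. In the siMITD1 libraries the scaffold AKAP12 rose from 7.24 to 23.5 FPKM.

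RBCK1 and ANKRD35 were far higher in their own control libraries than in the other control groups. RBCK1 was at 480.3 FPKM against 70.8 and 65.5, and 129 and 188 of 10597 genes were higher in shcontrol by as much or more. ANKRD35 was at 727.4 FPKM against 0 and 0.0064, a difference that only 1 gene, itself, reached. Genes lower by as much were not counted. Different scaling of the separately normalized tables would shift all genes by that much, but the largest median difference over all genes was 0.19 on the log2 scale. A broad gain or activation of the chromosome regions would raise the neighbours. Between shcontrol and sicontrol_for_siANKRD35, the only groups compared here, expressed genes within 500 kb had a median difference (own minus other) of −0.53 around RBCK1 (10 genes, the highest SRXN1 at 1) and −0.28 around ANKRD35 (13 genes, the highest TXNIP at 1.72). TXNIP also fell in siANKRD35 (−1.77), as it did in shRBCK1 (−0.72) and siMITD1 (−1.54). A median over neighbours cannot show a gain or activation of the gene alone, which stays open. Expression of the target from a construct in the cells of those comparisons was not tested and stays open, as does a basis for the group names other than the labels give.

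The interferon response list was lower in shRBCK1 than in shcontrol by a median of 2.99 on the log2 scale. Scaling between the libraries did not account for it, since the median was −2.89 at its highest under quantile normalization and median-ratio scaling. RNA of blood cells in shcontrol did not either: 17 marker genes had a mean of 0.2 FPKM there and 0.28 FPKM in shRBCK1 (the median, looked at first, was 0), 16 of them under 1 FPKM, and LAPTM5, the highest, went from 2.19 to 3.26 FPKM. A candidate explanation is an interferon response active in the shcontrol libraries, because the list stood above the other control groups by medians of 2.6 and 3.07 while shRBCK1 differed from them by −0.26 and −0.31, and the interferon genes IFNB1 (153 reads) and IFNL1 (53 reads), picked after their values were seen, had 0 reads each in shRBCK1. The other control groups are an uncertain baseline, since single genes differed widely between them. On the log2(FPKM + 1) scale the list gene BST2 was at 0.17 in sicontrol_for_siANKRD35, 7.31 in sicontrol_for_siMITD1 and 8.33 in shcontrol. GDF15, outside the list, was at 452 FPKM in sicontrol_for_siANKRD35 and 5.62 FPKM in sicontrol_for_siMITD1. Whether the cells of the 3 comparisons were alike was not tested. A direct effect of RBCK1 on the interferon response genes stays open, since the shcontrol libraries are the only control of that comparison.

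In the MITD1 comparison genes with particular 3′ UTR words were shifted: of 15190 seven-base words TCTTCAA (1328 genes, z −9.87) and TTCTTCA (1916 genes, z −9.82) ranked lowest and CGGAGAA (z 6.84) and TCGGAGA (z 6.82) highest, each permutation p = 0.001, the smallest the permutations can give. Seed pairing of one strand of the MITD1 duplex may account for the lower words: TTCTTCAA lies in exon 5 of the MITD1 coding sequence (chromosome 2, 99170556 to 99170563, minus strand; 22.1% of the seven-base words tested occur in the MITD1 transcript), genes with it were lower than genes with only a part of it by −0.049 (SE 0.02), and the words had z between −0.96 and 1.17 in the other comparisons. Base composition of the 3′ UTR would shift other orders of the same bases alike, but the 104 other orders of TTCTTCA had a median z of −0.45 (lowest −6.43). Seed pairing of a control duplex cannot be told apart from other causes for the higher words, with a difference of 0.032 (SE 0.07) over 57 genes with TCGGAGAA. The list calls at the preset correlation did not need genes with the words (highest camera adjusted p of the 3 lists without them 0.00039). They were lost in camera for ATF4, hypoxia and S phase, at adjusted p = 0.064, 0.14 and 0.064 with an estimated correlation. Other splits of the libraries gave 2 or 3 list calls at the preset correlation. Each kept part of the difference between the groups, so these calls do not bear on the list calls. A share of single decreases, ANXA1 among them, could come from seed pairing of the MITD1 duplex.

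The same scan, corrected as for MITD1 for length and GC content of the 3′ UTR, was run in the other comparisons. It gave lowest z −4.56 for TATTTAT (permutation p = 0.049) in the RBCK1 comparison and highest z 5.44 for ACGGGGT (permutation p = 0.001) in the ANKRD35 comparison. As measured, the medians went the other way, at 0.012 with TATTTAT against −0.003 without it and at −0.019 with ACGGGGT against 0.032 without it.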
